A study of Mus musculus with 15 samples.

How the data were processed

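Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done with an antibody against BAZ1B, also called WSTF, a bromodomain protein that partners ISWI-type chromatin remodelers. The tissue was the nucleus accumbens of male C57BL/6J mice, and punches of up to 10 mice were pooled for each replicate, per the labels' protocols. The series holds 15 samples in 5 groups of 3. The cocaine and saline groups, 6 libraries in all, were analysed; the 9 samples of the social defeat experiment were not analysed here. Cocaine mice received daily injections of 20 mg/kg, and libraries were read at 100 bp, per the labels' protocols.

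The analysis starts from 1 table of differential regions between cocaine and saline. It holds 381 regions with mm9 coordinates, and the submitters' processing notes also name CASAVA 1.8. The table's name gives diffReps as the tool of the region search and the short form nb, read here as its negative binomial test. Its version and thresholds, the aligner and the read filters are not given in the sources used here. The deposited signal of each region is a normalized read count for each of the 6 libraries, with group means beside it, per the file headers. The authors' log2 fold change of a region, cocaine over saline, is the log2 of the ratio of the deposited group means, with a largest deviation of 0.0061. The authors' p-value and adjusted p-value are given per region, and a further deposited p-value is given for the best window inside it. All 381 best-window p-values lie under 0.0001. The adjusted p-values equal a Benjamini-Hochberg adjustment over 14119 tests in 381 of 381 regions, within 0.1%. The gene, its RefSeq transcript, the annotation class and the direction of each region are the authors' own. "Gained" stands for a region the authors list as higher in cocaine and "lost" for one listed as lower.

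The header names 26 columns for 30 cells per line, since the treatment and the control count names each cover 3 library columns. The columns do not carry replicate numbers, so libraries are named by group and listed order. The design written before the data were examined assumed group values only; its comparisons of regions were run as written, and tests on the libraries were added once values per library were seen.

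Values in each library are whole multiples of the worth of 1 read, which was 1.93, 0.888 and 1.95 in the cocaine libraries and 0.860, 0.603 and 0.552 in the saline libraries. With these values 100% of the entries of every library came out whole, within 0.1 read, and reads were recovered. On simulated values the worth of 1 read was found within 0.1% in 6 of 6 libraries. The inverse of this worth is called relative depth, or depth, below. It equals sequencing depth only if the deposited counts were scaled by total reads, which the sources used here do not state. Total depth is unknown.

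Gained and lost regions were compared by an exact binomial test of the split, by Fisher's exact test for each annotation class, chromosome and gene list with Benjamini-Hochberg adjustment within each family, and by permutation tests of 100000 resamples for medians and for shared direction within genes. These tests were two-sided, and they describe the table: regions are not independent replicates. In simulated sets with medians 1 SD apart and with equal medians the permutation test was checked before use. For the libraries, limma was fitted to log2(value + 1) with a mean-dependent prior, adjusted over 14119 tests, with fold changes on the log2(value + 1) scale. edgeR's quasi-likelihood test was run on the recovered reads with the relative depths as library sizes and the same adjustment. These models see only regions the authors had already selected on the same 6 libraries, so their p-values are not independent evidence. In data simulated for cocaine against saline over 381 regions, with 200 changed and a dispersion of 0.02, limma called 25% of regions changed by 1 on the log2 scale and 84% of those changed by 2, and edgeR called 35% and 97%. Neither called any of the 181 unchanged regions there, whereas adjustment over the 381 regions alone let limma call 2 and edgeR 3 of them. The simulated regions were not selected and shared 1 dispersion, so these rates need not hold for the deposited regions.

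Named genes were fixed by a rule before the data were examined: the 10 regions with the smallest authors' p in each direction inside a named gene's promoter or body, with 1 region per gene; every gene with 3 or more regions; and up to 4 members of each of 18 gene lists, again by the authors' p. The members of 1 of these lists are not reported here. All 678 symbols of the lists were found in the GRCm38.p6 gene table by symbol or synonym; of the 110 genes of the regions, 106 matched by symbol and 3 by synonym. That table was used for names only. Enrichment over genes matched for length and region counts per megabase were not run, because no mm9 annotation was used here; repeats at the high-count regions were not checked for the same reason. Alternatives fixed in advance were stricter adjusted p thresholds of 0.05 and 0.01, a minimum absolute log2 fold change of 1, a minimum mean of 20 in the higher group, autosomes only, merging of regions within 5 kb, other class and list definitions, and leaving out each library. Means are given with the SD over 3 libraries. Software was R 4.3.3 with limma 3.58.1 and edgeR 4.0.16, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.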

Results

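BAZ1B occupancy was profiled by ChIP-seq in the nucleus accumbens, a striatal region central to reward, of mice given daily cocaine or saline. Each group had 3 libraries, described in the labels as independent biological replicates. Depth was read from the scaling of the deposited counts, relative to the deepest library. It was 28.5%, 62.1% and 28.2% in the cocaine libraries and 64.1%, 91.5% and 100% in the saline libraries. The group means were 39.6% and 85.2%. The comparison addresses where BAZ1B occupancy differs after repeated cocaine. Coordinates are mm9.

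The authors listed 223 regions with more BAZ1B signal in cocaine than in saline libraries, the gained regions, and 158 with less, the lost regions. Of these 381 regions, 17 have an adjusted p of 0.05 or more in the authors' deposited table, 11 of them an adjusted p of 1, and the libraries of the groups overlapped at 31. Among gained regions inside genes with the smallest authors' p were Anks1b, which encodes a postsynaptic scaffold protein, with 4.14-fold more signal, and the ryanodine receptor gene Ryr3, with 3.03-fold more. Their lost counterparts included Gabrb1, a GABA-A receptor subunit gene, with 6.16-fold less signal, and Lrp1b, a gene of the LDL receptor family, with 6.19-fold less. Without the cocaine library listed as 2, which left 1 cocaine read at each, the folds were 17.33 for Gabrb1 (95% counting interval 3.0 to 694.6) and 19.15 for Lrp1b (3.4 to 770.7). All 3 cocaine libraries lay outside the range of the 3 saline libraries at each of these 4 regions. The groups were apart at 350 of the 381 regions, which the authors had selected on these libraries. Gained regions made up 58.5% of the table (exact binomial p = 0.00102 against an even split). Without the 63 regions whose higher group mean was 60 or more, the share was 54.7% (exact binomial p = 0.104), with 174 gained and 144 lost. Depth differed between the groups and the regions were selected on these libraries, so no effect of cocaine need not give an even split. These p-values therefore do not show that cocaine mainly adds BAZ1B signal.

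Most regions were short and held few reads. Outside the 63 high-count regions, gained regions had a median normalized read count of 20.0 in cocaine and 7.35 in saline, a median 2.68-fold difference. Lost regions had medians of 4.40 in cocaine and 16.6 in saline, a median 3.88-fold difference. These rested on a median of 42 reads in cocaine and 35 in saline for gained regions, and of 10 and 78 for lost regions. The folds of gained regions therefore depend on how the counts were scaled. The cocaine and saline libraries did not overlap at any of these 318 regions, where chance gives 10%, but the authors had selected the regions on the same libraries. Over all regions the median absolute log2 fold change in the authors' deposited table was 0.56 larger for lost than for gained regions (permutation p = 1e-05, the smallest the resamples can give). The difference reversed to -1.05 among the regions with a mean of at least 20 in the higher group. Of the 27 lost regions there, 14 were high-count regions in the Sfi1 block of chromosome 11, so this block set the lost median. Their median absolute log2 fold change was 0.135, against 0.25 at the 49 high-count gained regions.

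**Figure D1:**
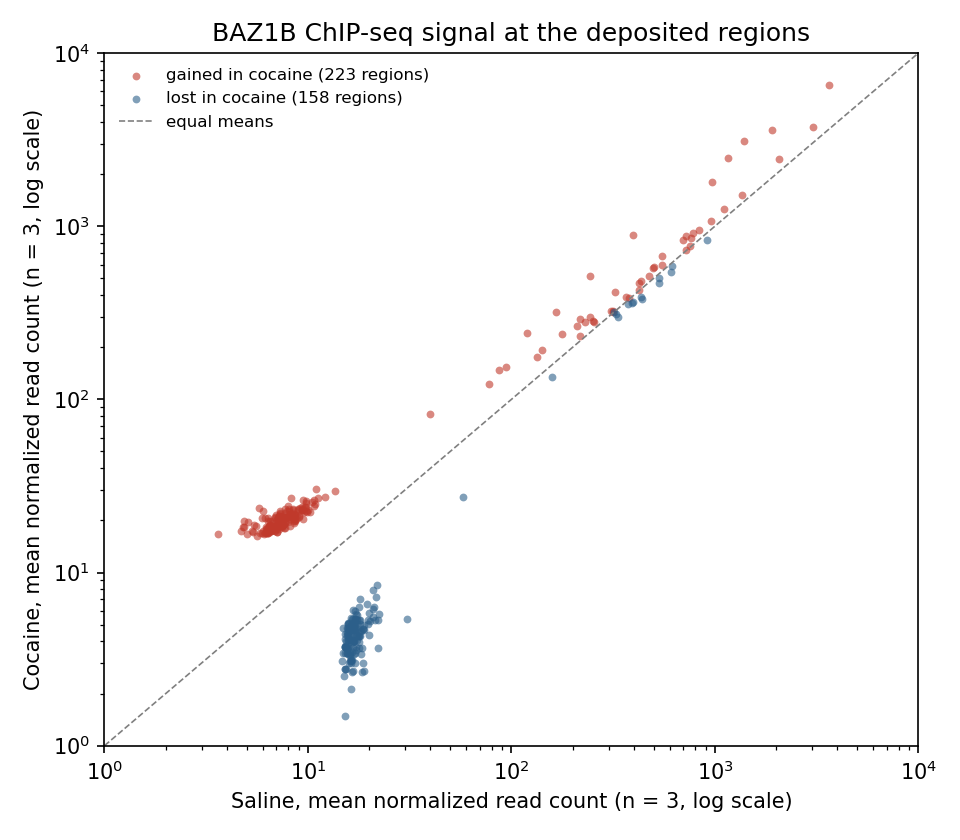
Mean normalized read count of each region in saline (horizontal) and cocaine (vertical), both on log scales, with 3 libraries per group; points are the 223 gained and 158 lost regions and the dashed line marks equal means. Low-count gained and lost regions form separate clouds, and the 63 regions with a higher group mean of 60 or more lie near the line or above it.

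Among the 10 gained genes with the smallest authors' p, Sfi1 aside, signal was higher in every cocaine library than in every saline library. The Anks1b region (chromosome 10, 90001001 to 90002300, gene body, NM_001128086) had 23.7 ± 4.46 normalized reads in cocaine and 5.73 ± 3.64 in saline (SD, n = 3). The Ryr3 region (chromosome 2, 112834701 to 112836000, gene body) had 24.3 ± 7.45 and 8.00 ± 2.15. Rbms3, an RNA-binding protein gene, had 30.2 ± 10.5 in cocaine and 10.98 ± 2.29 in saline on chromosome 9 at 116743501 to 116744800. Nfib, a transcription factor gene of the nuclear factor I family, had 21.9 ± 2.08 and 7.29 ± 3.33. Tln2, a talin gene linking integrins to actin, was 3.02-fold higher in cocaine. Slc9a9, a sodium-proton exchanger gene, was 3.26-fold higher, and the mitochondrial carrier gene Slc25a24 was 2.91-fold higher. Ccdc141 and Skint6 were 2.87-fold and 3.00-fold higher. In the authors' deposited table the adjusted p was 0.000409 for Anks1b and 0.00147 for Skint6.

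**Figure D2:**
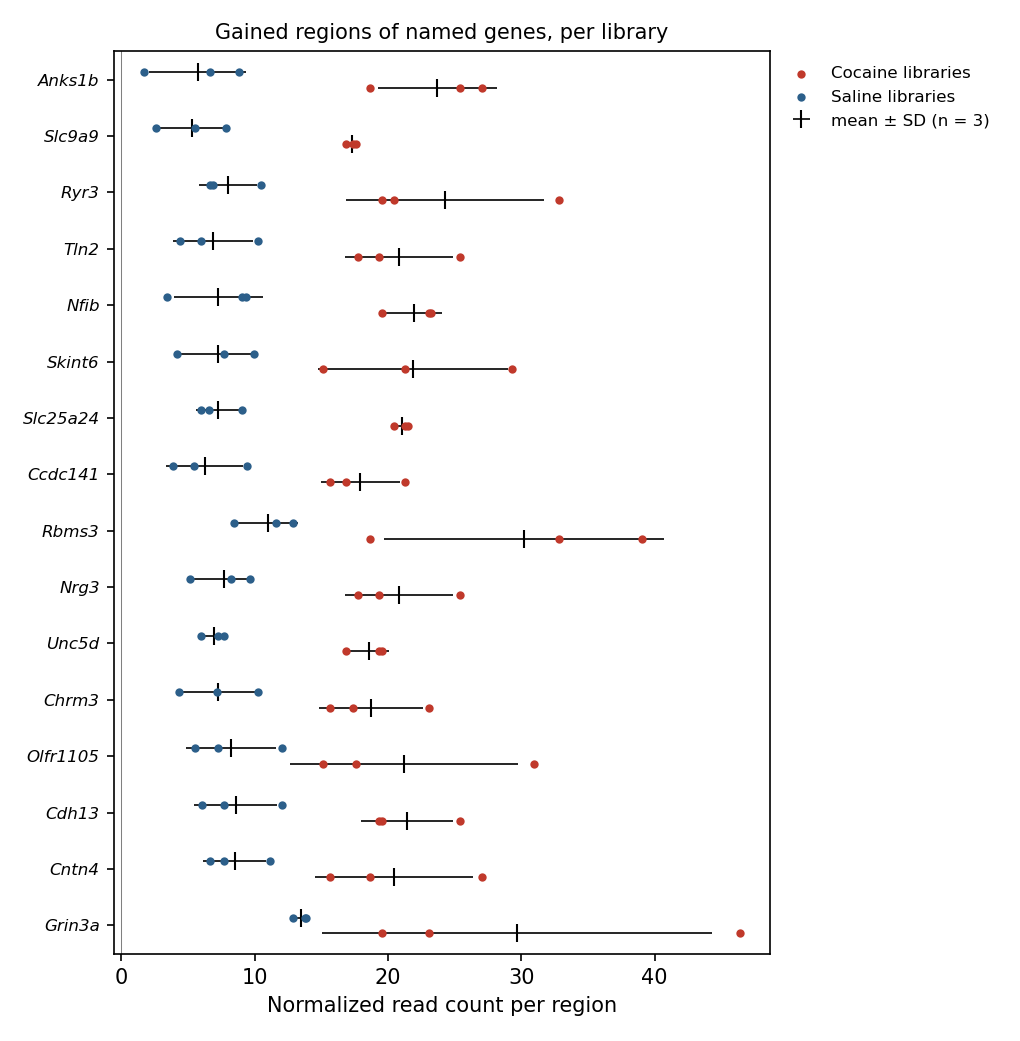
Normalized read counts per region (horizontal) in each cocaine and saline library at 16 gained regions of the named genes reported here, ordered by fold; points are libraries and black bars give the mean ± SD (n = 3). The folds run from 4.14 at Anks1b to 2.19 at Grin3a, and at all 16 regions every cocaine library lies above every saline library.

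Of the 10 lost genes with the smallest authors' p, those other than Sfi1 and 4931408C20Rik rested on 7 to 13 cocaine reads each. The Lrp1b region (chromosome 2, 41724801 to 41725900, gene body, NM_053011) had 3.02 ± 3.67 normalized reads in cocaine and 18.7 ± 1.02 in saline (SD, n = 3), resting on 9 and 87 reads. The Gabrb1 region (chromosome 5, 72472001 to 72473100, gene body) had 2.72 ± 3.18 and 16.7 ± 1.73, resting on 8 and 78 reads. The zinc finger gene Zfp407 was 5.58-fold lower in cocaine, Sel1l2 was 5.40-fold lower and Prr16 was 4.72-fold lower. A pair of oogenesin genes on chromosome 4, Oog4 and Oog3, were 5.19-fold and 3.34-fold lower. The noncoding gene D930032P07Rik was 3.92-fold lower. Outside the high-count regions, the lost region with the most signal after cocaine lay in the promoter class at 4931408C20Rik on chromosome 1, with 27.3 ± 7.64 in cocaine and 57.7 ± 3.46 in saline. A cocaine library was listed at 0 in 5 of the 9 genes other than Sfi1, Lrp1b and Gabrb1 among them, so these folds are loosely bounded by the depth. Without the cocaine library listed as 2 the fold was 19.15 at Lrp1b (1 read, 95% counting interval of the pooled reads 3.4 to 770.7), 17.33 at Gabrb1 (1 read, 3.0 to 694.6) and 9.38 at Sel1l2 (2 reads, 2.5 to 78.2). Without the one listed as 3 it was 12.4 at Prr16 (3 reads, 3.0 to 44.6), 9.18 at Oog4 and 3.72 at Zfp407.

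**Figure D3:**
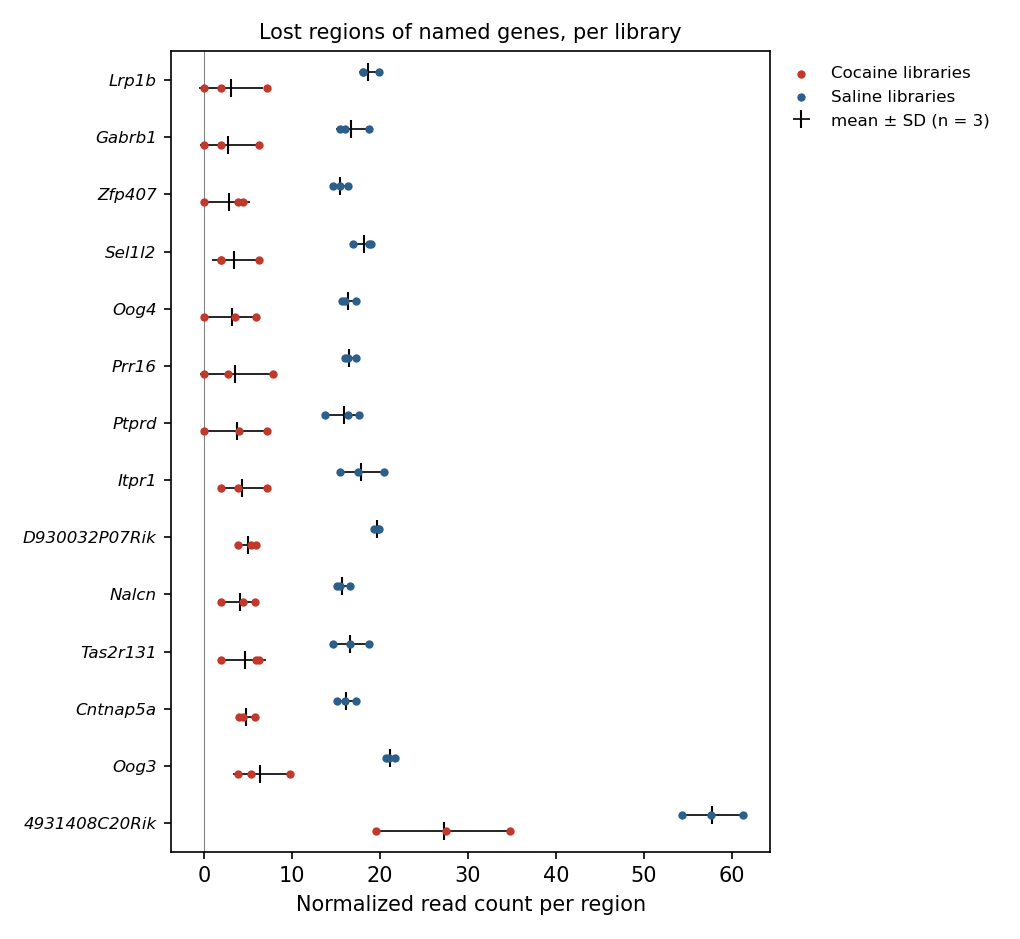
Normalized read counts per region (horizontal) in each cocaine and saline library at 14 lost regions of the named genes reported here, ordered by fold; points are libraries and black bars give the mean ± SD (n = 3). The folds run from 6.19 at Lrp1b to 2.12 at 4931408C20Rik, and every cocaine library lies below every saline library.

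Genes of the 18 fixed lists appeared in both directions, 11 with a gained and 7 with a lost region. Among synaptic adhesion and scaffold genes, Cdh13, a cadherin gene, was 2.49-fold higher in cocaine, and Cntn4, a contactin gene, was 2.40-fold higher, and Lsamp was the other of the 3 gained members. The 2 lost members were Ptprd, a receptor phosphatase gene with 4.33-fold less signal, and Cntnap5a, with 3.41-fold less. The Ptprd fold was 2.89 without the cocaine library listed as 1 and 8.13 without the one listed as 2 (2 reads, 95% counting interval 2.2 to 70.0). With 5 members, the most of any list, even 5 lost and 0 gained genes would give a Fisher's exact adjusted p of 0.119 over 18 lists, so the share could not be tested (observed adjusted p = 1.0).

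Calcium and sodium channel genes held 1 gained and 2 lost members. Ryr3 was gained, whereas Itpr1, the gene of an inositol trisphosphate receptor that releases calcium from the endoplasmic reticulum, was 4.13-fold lower in cocaine at 4.31 ± 2.60 against 17.8 ± 2.47 (SD, n = 3). Nalcn, a sodium leak channel gene, was 3.86-fold lower. Axon guidance genes had 2 gained members, Unc5d, a netrin receptor gene with 2.66-fold more signal, and the cell adhesion gene Chl1. Among receptor genes, the NMDA receptor subunit gene Grin3a was 2.19-fold higher at 29.7 ± 14.6 against 13.5 ± 0.538, and the muscarinic receptor gene Chrm3 was 2.58-fold higher. Gabrb1 was the 1 GABA list member. Nrg3, which encodes a ligand of ErbB receptors, was 2.71-fold higher. Of the chemoreceptor genes, the promoter-class region of Olfr1105 was 2.57-fold higher and that of Tas2r131 was 3.56-fold lower.

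No region was listed for 9 of the 18 lists: immediate early genes, dopamine signalling, potassium channels, chromatin regulators, and markers of medium spiny neurons, interneurons, astrocytes, oligodendrocytes, and microglia with endothelium. The smallest unadjusted Fisher's exact p of any list was 0.378, for the GABA list. None of the 18 lists held enough genes for a difference between gained and lost genes to pass.

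Regions in gene bodies or promoter classes made up 35.0% of gained and 32.9% of lost regions, and 251 of 381 regions were intergenic. Gene bodies alone held 32.3% of gained and 29.7% of lost regions. Only 11 regions fell in the promoter classes. The pericentromere class held 25 gained and 0 lost regions (Fisher's exact adjusted p = 5.51e-06), and no other class passed. No repeat annotation was used here, so satellite repeats were not checked as a source of the pericentromeric and gene-desert signal. Chromosome Y held 23 gained and 0 lost regions (adjusted p = 6.58e-05), 20 of them pericentromeric, and no other chromosome passed. The remaining pericentromeric gains lay on chromosomes 9 and 12. No class or chromosome passed among autosomal regions alone, which hold 5 pericentromeric regions, or after merging regions within 5 kb. The same held among regions with an absolute log2 fold change of at least 1, which include no pericentromeric or chromosome Y region.

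The listed chromosome Y regions were slightly higher in cocaine. In the block from 2850801 to 2902600, with 14 regions, the summed count was 12127 ± 574.0 in cocaine and 10642 ± 308.0 in saline (SD, n = 3), a 1.14-fold difference. In the block from 2780201 to 2796500 it was 6667 ± 495 and 5548 ± 207, a 1.20-fold difference. These sums cover only regions listed as gained, so their direction was set by the selection. Cocaine and saline libraries were apart at 18 of the 23 chromosome Y regions, where chance gives 10%, but the regions were selected on the same libraries and 19 of them lie in these 2 blocks. Neither limma nor edgeR's quasi-likelihood test called any of the 23 after adjustment (0 by each), with 12 and 13 at an unadjusted p under 0.05.

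Larger gains at high counts lay in 14 autosomal regions, with 1.34-fold to 2.25-fold more signal in cocaine, and in 2 of 3 chromosome X regions. edgeR called 3 of the 14 and limma 0, with all 14 at an unadjusted p under 0.05 by each. At chromosome 2, 98505101 to 98508400, a gene desert, counts were 3115 ± 1235 in cocaine and 1383 ± 359 in saline (SD, n = 3). At the chromosome 9 pericentromere, 2999101 to 3039200, the 4 regions, all listed as gained, summed to 12091 ± 4153 and 6603 ± 1035, and the selection set the direction of this sum too. The Chl1 gene body region (chromosome 6, 103598201 to 103600200) had 514 ± 176 and 244 ± 57.5. The excess came from 2 of the 3 cocaine libraries, the shallowest of the 6: their median folds over the saline mean were 2.21 and 2.28, against 1.11 in the other cocaine library. That library lay inside the saline range at 11 of the 14 regions. On chromosome X, the region at 139917601 to 139918600 had 82.5 ± 40.7 in cocaine and 39.6 ± 10.8 in saline and was not called by edgeR. The one at 53240101 to 53241100 had 192.6 ± 12.1 and 140.6 ± 10.2 and was called, and the third was 1.11-fold higher.

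**Figure D4:**
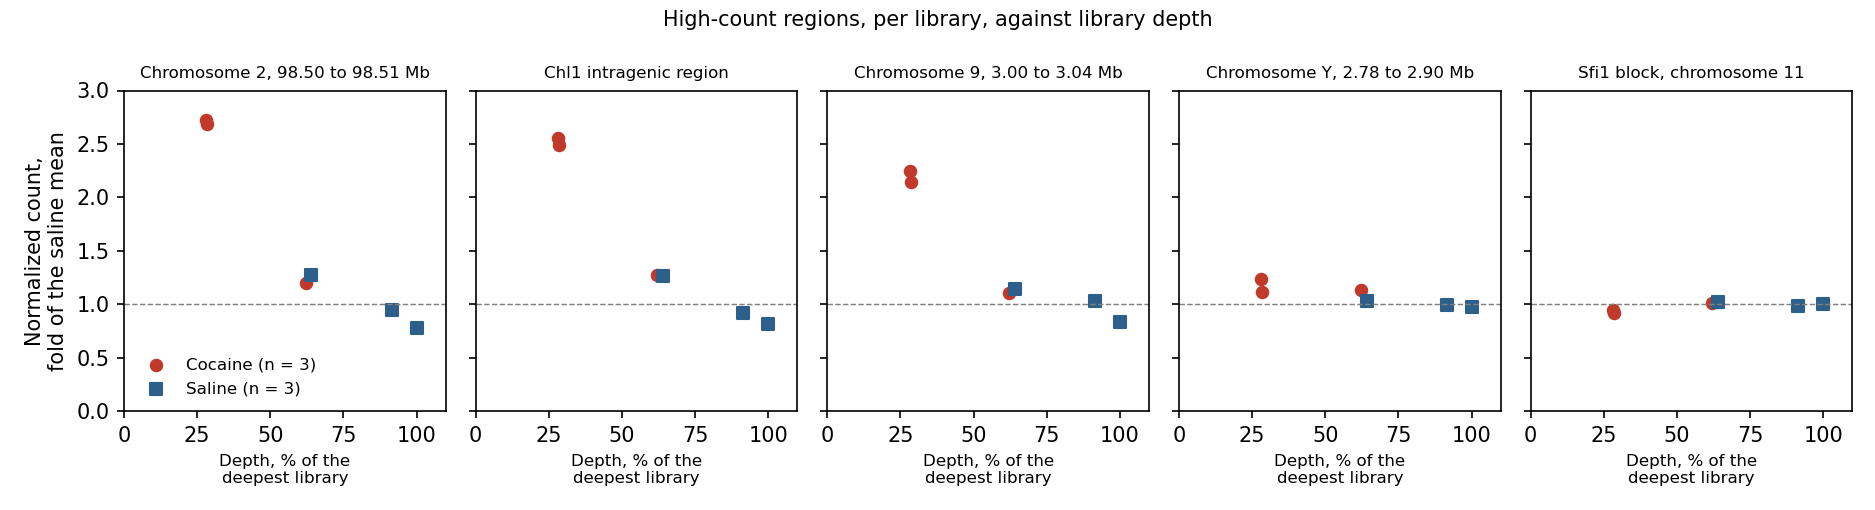
Normalized count as a fold of the saline mean (vertical) against library depth as a percentage of the deepest library (horizontal) in 5 high-count locations, with blocks summed over their listed regions; circles are the 3 cocaine and squares the 3 saline libraries. At chromosomes 2 and 9 and at Chl1 the 2 cocaine libraries of 28.5% and 28.2% depth stand above the rest, while the values at chromosome Y and the Sfi1 block lie nearer to 1.

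Sfi1, whose protein binds centrin at the centrosome, was the gene with most regions, 19, in both directions. The 23 regions of its block (chromosome 11, 3027901 to 3099600) summed to 9398 ± 475 normalized reads in cocaine and 9773 ± 178 in saline (SD, n = 3). This sum joins 9 regions listed as gained and 14 listed as lost, with 4 overlapping pairs that share reads, so it does not measure the block as a whole. In the authors' deposited table the Sfi1 region at 3084701 to 3086900 has a log2 fold change of 0.03 and an adjusted p of 6.93e-07. On its recovered reads, 1598 in cocaine and 3309 in saline, edgeR's quasi-likelihood test gave an unadjusted p of 0.696. Rbms3 and Cep112 each had 2 gained regions. These 2 of the 3 genes with several regions shared a direction (permutation p = 0.265). Agreement in both is the most that these 2 genes could show, so the test could not decide whether regions of a gene share a direction.

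Across the table, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 14119 tests called 286 of 381 regions, and 27 of the 33 regions of the named genes reported here. The exceptions were both Sfi1 regions, Ptprd, Grin3a, Olfr1105 and Skint6. limma called 0 at the same adjustment, with a smallest adjusted p of 0.053 and 347 regions at an unadjusted p under 0.05. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1.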

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

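The high-count limit of 60, the requirement of groups apart, and the tests on libraries with their alternatives were chosen after seeing the data; the other settings were fixed before. No paired analysis was possible because the library columns carry no replicate numbers. Stricter adjusted p thresholds changed no call or direction among the compared results, and the fixed lists held too few genes for any list to pass under any list or region setting run. A minimum absolute log2 fold change of 1 left a gained share of 55.6% (exact binomial p = 0.0517), with 0 classes and 0 chromosomes differing; without regions of a mean of 60 or more the share was 54.7% (p = 0.104), again with 0 classes and 0 chromosomes. A mean of at least 20 in the higher group left 136 gained and 27 lost regions, 0 differing classes, 1 gene with several regions and 0 of them of 1 direction, and 7 gained and 0 lost list genes. It reversed the median differences, to -1.05 for the absolute log2 change (lost minus gained) and -131 for the mean count (gained minus lost, main value 3.55), and 14 of the 27 lost regions that pass it have a mean of 60 or more. The share in gene bodies or promoter classes, gained minus lost, also changed sign there, from 2.1 to -19.5 percentage points (Fisher's exact p = 0.742 and 0.0769). Autosomes only, and merging within 5 kb, each gave 0 differing classes and 0 chromosomes, and joining the intergenic classes gave 0 classes. Promoter regions alone left 1 gained and 1 lost list gene; allowing any gene-named region added none. Leaving out each library left 220 to 223 gained and 156 to 158 lost regions in their direction, but at the 350 regions whose groups do not overlap no direction could turn, so this says nothing about stability. At the 14 autosomal high-count regions the median fold, 1.87 with all libraries, ran from 1.67 to 2.25. limma called 0 regions with either pseudocount and without each library, against 346 when adjusted over the 381 regions alone and 286 with edgeR; the cause of the gap between tools was not tested. Single-gene values for the genes reported here were run with edgeR, with the other pseudocount and without each library. Of these, 237 stayed on their side of the threshold with their direction and 27 passed it with edgeR. limma called 0 regions in each of its settings among these, and no direction could turn where groups were apart. The 237 therefore do not measure stability. Length-matched list enrichment was not run. The shallow cocaine libraries limit the lost regions most, with a median of 10 cocaine reads.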

Other observations

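The tests on single libraries, on library order and on counting noise, and the test of cadherin genes, were chosen only after the values were seen; those on simulated windows, edgeR in the Sfi1 block, splits of the libraries and gene length were set before their results.

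Cadherin genes, which encode calcium-dependent adhesion proteins, had 3 gained and 0 lost members, a group singled out after its values were seen. Besides Cdh13, the Cdh19 region on chromosome 1 (112832401 to 112833500) had 17.2 ± 1.52 normalized reads in cocaine and 5.36 ± 3.20 in saline, and the Cdh9 region on chromosome 15 (16739601 to 16740600) had 17.5 ± 1.96 and 6.87 ± 2.16 (SD, n = 3). The hypothesis that cadherin genes are over-represented among gained against lost genes could not be tested at this size, since all 3 members gained is the most extreme split and gives a Fisher's exact p of 0.288 over 69 gained and 42 lost genes. Cep112, a centrosomal protein gene, had its 2 gained regions on chromosome 11, at 2.58-fold and 2.67-fold more signal. Genes with a gained and with a lost region had median annotated lengths of 169.8 and 159.9 kb (permutation p = 0.961). The bound set beforehand for that test, a p of at least 0.05, was too weak to exclude a difference in length, since a missed threshold does not show equality.

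The gain at the 14 autosomal high-count regions, of which edgeR called 3, came from 2 of the 3 cocaine libraries: the remaining one lay inside the saline range at 11 regions, a count that describes the pattern and tests no explanation of it. The median folds of the cocaine libraries over the saline mean were 2.21, 1.11 and 2.28 in listed order. These folds cannot decide on an equal effect of cocaine in all 3 libraries, since the 2 higher libraries are also the 2 shallowest. Only 3 of the 14 regions had every cocaine library above every saline library, but that count turns on the same 1 library. A difference in depth may contribute: within saline alone the libraries fell in the order of their depth at 13 of the 14 regions, where 1 given order comes up by chance 16.7% of the time in independent regions, and these regions may share 1 source of reads. The cocaine and saline libraries of nearest depth, 62.1% and 64.1%, had a median ratio of 0.95 there, from 0.84 to 1.13, while an effect of cocaine that differs between pools of mice stays open, since both shallowest libraries are cocaine.

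Falls were larger than gains by 0.535 in median absolute log2 change outside the high-count regions. Depth and selection with no difference between groups could give part of this gap: simulated windows of equal mean, held to the fewest reads seen in each library and to an exact binomial test, gave a median gap of 0.30 over 5 background levels, from 0.25 to 0.33. Those floors came from the same gained and lost regions, so the simulated gap is not independent of the observed one and cannot show how much selection explains. In the higher group the spread between libraries averaged 0.55 of counting noise at gained and 0.29 at lost regions, against 1.02 and 1.21 in the lower group, and a requirement on every library of that group is a candidate explanation. No biological explanation of the gap was tested.

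The Sfi1 block pairs small deposited p-values with almost no change. Of its 23 regions, 13 have an adjusted p under 0.05 in the authors' deposited table, and 0 of these 13 passed edgeR's test, with a smallest unadjusted p of 0.0585. Counting noise taken as the only error is argued against, because an exact binomial test on the recovered reads gave p under 0.05 at only 3 of the 13. It did so at 350 of 351 such regions elsewhere, but the authors' selection on the same libraries made that likely. A different behaviour of the deposited test at these counts may contribute, but count level alone does not account for the small p-values. The block's other 10 regions, at counts that overlap those of the 13, have a deposited adjusted p of 0.05 or more. The region at 3096301 to 3097300 has a log2 fold change of 0.0 and a deposited p of 1.53e-10. The one at 3098001 to 3099600 has -0.22 and a deposited p of 0.0892, with an exact binomial p of 0.00154. The table's name points to the negative binomial test of diffReps, which allows for more spread than counting noise. Its version and options are not given in the sources used here. An effect of cocaine on the block as a whole was left open, since the ratio of 0.96 sums 9 regions listed as gained and 14 as lost, whose directions cancel, with 4 overlapping pairs.

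limma called 0 regions in the real split of the 6 libraries and 13 in the highest other split. With a real count of 0, all 10 splits give at least as many by construction, so this count decides nothing. At an unadjusted p under 0.05 the real split gave 347 and the highest other 17, in regions the authors selected on the real groups, and edgeR called 286. That highest other split set the 2 shallowest cocaine libraries and the saline library listed as 1 against the rest. With the saline library listed as 2 instead, limma called 10 regions, and 16 had an unadjusted limma p under 0.05. With the one listed as 3 these counts were 0 and 15. A structure of the samples behind these splits was not tested. With 10 splits the share cannot fall under 0.05.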
